A study of Mus musculus with 3 samples.

How the data were processed

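Total RNA of fully grown mouse oocytes was cut from polyacrylamide gels in 3 windows, ligated to adapters, amplified and sequenced on an Illumina 1G instrument, per the labels. Per the labels' design text, the 19-24 and 24-30 nt windows were one way of dividing the RNA and the 19-30 nt window another, each processed on its own. The deposited files hold other values than counts: single reads with a quality per base, not trimmed of the 3' linker. Any aligner, genome build or filter used by the authors is not given in the sources used here. The planned unit was therefore replaced by counts of reads made here, and the planned comparisons without tests were kept.

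Reads of 26 nt (19-24 and 24-30 nt libraries) and 36 nt (19-30 nt library) were trimmed of the linker CTGTAGGCACCATCAAT, with an overlap of at least 4 and 6 called bases and up to 20% mismatches. In 26 nt reads an insert could be sized up to 22 nt, and a read in which no linker was found was taken as 23 nt or longer. Linker-only reads made up 7.12%, 0.653% and 10.8% of the 19-24, 24-30 and 19-30 nt libraries. In 36 nt reads, 313373 in which no linker was found were taken as inserts over 30 nt and set aside. Whether a linker was missed in shorter inserts was not tested. On 5000 simulated reads per length with 2% base errors, the lowest share of exact lengths was 92.6% for 26 nt reads with inserts of 18 to 22 nt and 99.3% for 36 nt reads. That error rate is too low for the 26 nt reads, and at cycles 21 to 23 also for the 36 nt reads (5.29%, 13.6% and 19.8% differing bases). A repeat with measured differences was made for the 26 nt libraries only, so the 99.3% is not tested at these rates. With the differences measured at cycles 21 to 23, the lowest share was 80.6% for the 19-24 nt and 83.1% for the 24-30 nt library, both at 21 nt. The other simulated reads of 18 to 22 nt inserts were left unsized, which lowers shares of short inserts, and up to 1.20% of 23 to 26 nt inserts were given a shorter length. Uncalled bases were not simulated, and this repeat was added later. They occurred in 177489 reads of the 19-24 nt, 171655 of the 24-30 nt and 1010 of the 19-30 nt library. In the linker they can leave an insert unsized, and at base 19 or 20 of an insert they leave it without a match.

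Inserts were compared with the 141767 transcripts of GENCODE M21 (GRCm38), on both strands, with 10 nuclear tRNA and 2 rRNA sequences entered by hand, and placed on the genome through the exons. No genome sequence was used, so a unique match means a single place among annotated transcripts, and introns, intergenic sequence and repeats were not analysed here. The first 20 nt had to match perfectly (the whole insert at 18 or 19 nt). Whole inserts were not required because base calls failed at cycle 21 of the 26 nt reads: there 43.4% of bases of singly matching reads differed from the transcript in the 19-24 nt library and 30.4% in the 24-30 nt library, against 5.29% in the 19-30 nt library. The later cycles did not show this failure, with 12.7%, 3.68% and 13.6% at cycle 22, and 8.44% in the 24-30 nt against 19.8% in the 19-30 nt library at cycle 23. This choice was made after the data were examined. Close family members that do not differ within the first 20 nt, such as Mirlet7c-1 and Mirlet7c-2, share reads and are uncertain. Reads of 18 or 19 nt can be shared more widely. A read with several matches was weighted by 1 over their number, and reads with more than 1000 were set aside, as were low-complexity reads and reads with an uncalled base among the first 18. Reads of 3 bacterial tRNAs entered by hand, and reads with either of a pair of sequence motifs taken as those of synthetic size markers, were counted apart. The hand-entered sequences were written from general knowledge, without a database, and together with the motifs they were chosen after the abundant unmatched reads had been seen, so that tRNA, rRNA and bacterial counts are lower bounds. Reads without a match made up 47.4%, 53.5% and 49.6% of usable reads in the 19-24, 24-30 and 19-30 nt libraries.

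Each place of a read took the first class that applied, and for first bases and lengths the read took the first over its places: bacterial tRNA, microRNA, tRNA, rRNA, snRNA or snoRNA, other small RNA, then coding, pseudogene and long non-coding sense, then antisense in that order. Short reads were those of the 19-24 nt library and those sized at up to 24 nt elsewhere, and other reads were long. Overlaps used distinct 5' ends of uniquely matching reads outside structural RNA, and unsized reads of the 26 nt libraries counted as long. Clusters are restricted to annotated exons.

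There was 1 library per window, so no test, p-value or count of changed genes is given. Shares have 95% Wilson intervals, levels exact Poisson intervals and ratios conditional binomial intervals, all for counting error only. A fold against a count of 0 uses a floor of 3 counts, which lowers the fold but does not cover counting error. Against 1 to 3 reads the ratio is given with its interval. Hairpin ratios were ranked with counts below 3 raised to 3. Random lists were drawn within 5 bins of mean level. Counting was tested on simulated 22 nt antisense reads of 400 coding genes at a mean of 40 reads, with 200 genes changed 4-fold. At their own gene a median of 97.9% of these reads was counted, the median recovered fold was 3.96 for the 100 genes raised 4-fold and 0.251 for the 100 lowered, and 97% of the intervals of each group held the true fold. For the 200 unchanged genes the median was 1.03, with 99% of intervals holding the true fold. The simulated reads had no base errors and came from random places of random coding genes. Many named genes have antisense reads with several matches (3.72% at a single place before weighting for D10Wsu102e), so this recovery does not carry over to them.

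Fixed before the data were examined were the comparisons, the lists and the rule for named items. Named were the 10 hairpins with most reads in each library, the 5 highest and 5 lowest ratios of the 19-24 to the 24-30 nt library among hairpins with at least 100 reads, members of fixed microRNA lists with at least 10 reads as counts with examples, the 15 coding genes with most short antisense reads (at least 50), the 5 with most long ones, every parental gene, the 10 clusters with most short and the 10 with most long reads, and the 5 most frequent sequences per library. Clusters left out reads of microRNA, tRNA, rRNA, snRNA and snoRNA genes. List ratios without the member with most reads were added later. Among the granulosa and stroma list, Mir21a is a microRNA of many cell types. Other settings tried were distinct sequences, unique matches, every match in full, other scalings, cluster settings and overlap weights, and matching over the first 18 nt or the whole insert was added later. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0, pandas 2.3.3, matplotlib 3.10.9.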

Results

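Small RNAs of fully grown mouse oocytes, the large oocytes that fill the ovarian follicle before ovulation, were sequenced from 3 gel windows. The females had received 5 IU of PMSG, a gonadotropin that drives follicle growth, 48 hours earlier. The windows were 19-24 nt, 24-30 nt and 19-30 nt, with 1 library each, so no difference between libraries has a replicate check. Intervals are 95% intervals of the counting error in 1 library and leave out PCR and preparation. The 19-24 nt library held 764539 reads, the 24-30 nt library 1484509 and the 19-30 nt library 943811. Usable inserts of at least 18 nt numbered 702839, 1471458 and 438645, of which 321454 (45.7%, Wilson interval 45.6 to 45.9), 595384 (40.5%, 40.4 to 40.5) and 149374 (34.1%, 33.9 to 34.2) matched an annotated mouse transcript, tRNA or rRNA over their first 20 nt. Levels are given as RPM, reads per 1000000 of these matched reads. A count of 0 allows up to 9.33, 5.04 and 20.1 RPM in the 19-24, 24-30 and 19-30 nt library.

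The first comparison asked which RNA lengths each gel window held. The 19-30 nt library peaked at 22 nt, with 23.2% of its usable reads (23.1 to 23.3), and inserts of 20 to 23 nt made up 56.1% (55.9 to 56.2). Among reads that matched mouse sequence this share was 78.7% (78.5 to 79.0), while 25 to 30 nt reads, the size of piRNAs, made up 12.5% (12.4 to 12.7). A second peak at 28 nt held 13.9% of the usable reads of that library and 1.90% of its matched reads (1.84 to 1.97). In the 24-30 nt library 98.4% of usable reads were taken as 23 nt or longer. In the 19-24 nt library 44.0% were sized at 22 nt or shorter (43.9 to 44.2), 22 nt again being the most frequent length that could be read, with 23.1%. Reads of the 19-24 and 24-30 nt libraries were 26 nt long, so that inserts of 23 nt or longer could not be sized there. The 19-30 nt library had 36 nt reads from another run, and library and run cannot be told apart.

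**Figure D1:**
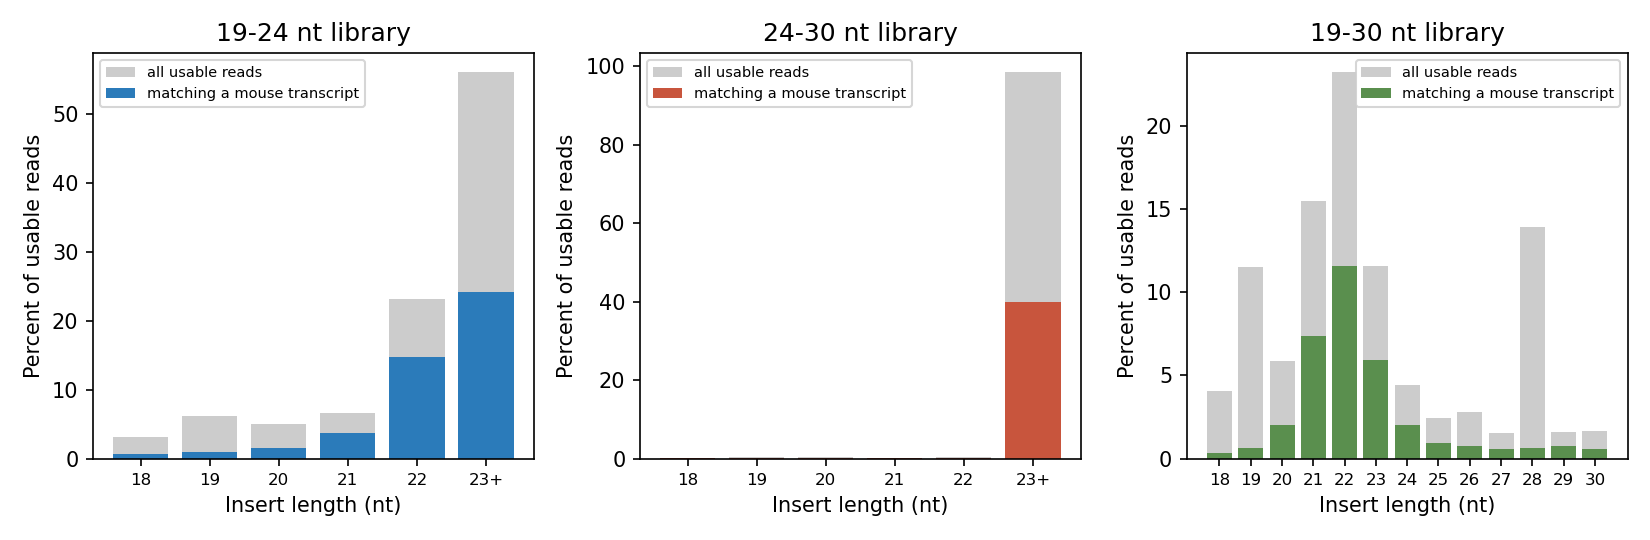
Percent of usable reads (vertical axis) by insert length in nt (horizontal axis) for the 3 libraries; grey bars are all usable reads and coloured bars the reads matching mouse sequence. The 28 nt peak of the 19-30 nt library is grey, with 1.90% of its matched reads at that length.

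MicroRNAs, endogenous siRNAs and piRNAs often start with uridine, and the first base was compared between lengths. Among matched reads outside microRNA, tRNA, rRNA and other small RNA genes, 74.1% of the 25 to 30 nt reads of the 19-30 nt library started with U (73.4 to 74.7), against 58.2% of its 20 to 23 nt reads (57.9 to 58.5). The long reads of the 24-30 nt library gave 73.3% (73.1 to 73.5), and the 19 to 22 nt reads of the 19-24 nt library 52.3% (51.8 to 52.9). Over all usable reads, mouse match or not, the order within the 19-30 nt library was the opposite: 28.6% of 25 to 30 nt reads (28.3 to 28.9) and 58.0% of 20 to 23 nt reads (57.8 to 58.2) started with U. The 28 nt reads, with 6.42% U, set the low value. The corresponding shares over all usable reads were 48.0% at 23 nt or longer in the 24-30 nt library and 44.8% at 19 to 22 nt in the 19-24 nt library. The restriction to matched reads was chosen after the data were examined.

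The libraries differed in the kinds of RNA they held. MicroRNAs made up 76.8% of matched reads in the 19-24 nt library (76.7 to 77.0), 16.9% in the 19-30 nt library (16.7 to 17.1) and 3.96% in the 24-30 nt library (3.91 to 4.01). Fragments of rRNA (37.1%, 37.0 to 37.2) and tRNA (16.2%, 16.1 to 16.3) led the 24-30 nt library. A single 5.8S rRNA fragment gave 145485 of its reads (9.89% of usable reads), and a tRNA-Glu-CTC fragment 65755 (4.47%). In the 19-30 nt library the leading classes were the sense strand of long non-coding RNAs (19.5%, 19.3 to 19.7) and of coding genes (17.8%, 17.6 to 18). This order depends on sharing a read among its matches: with 1 class per read coding sense took 77698 of the 149374 matched reads and long non-coding sense 18684, and among uniquely matching reads microRNA made up 34.2%. The coding antisense class, at places where no earlier class applied, made up 11.9% there (11.7 to 12.0), against 2.71% in the 19-24 nt library (2.66 to 2.77) and 4.40% in the 24-30 nt library (4.35 to 4.45). Among uniquely matching reads these shares were 9.0%, 1.36% and 0.953%, which turned the order of the 19-24 and 24-30 nt libraries. The 2 most frequent sequences of the 19-24 nt library were those of Mir322 (26154 reads) and Mir22 (17683 reads), and the fifth was that of Mirlet7c-1 (9067 reads). The other leading sequences were taken as size markers or bacterial tRNA fragments, or had no mouse match. Class shares rest on transcripts, since introns, intergenic sequence and repeats were not searched here.

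**Figure D2:**
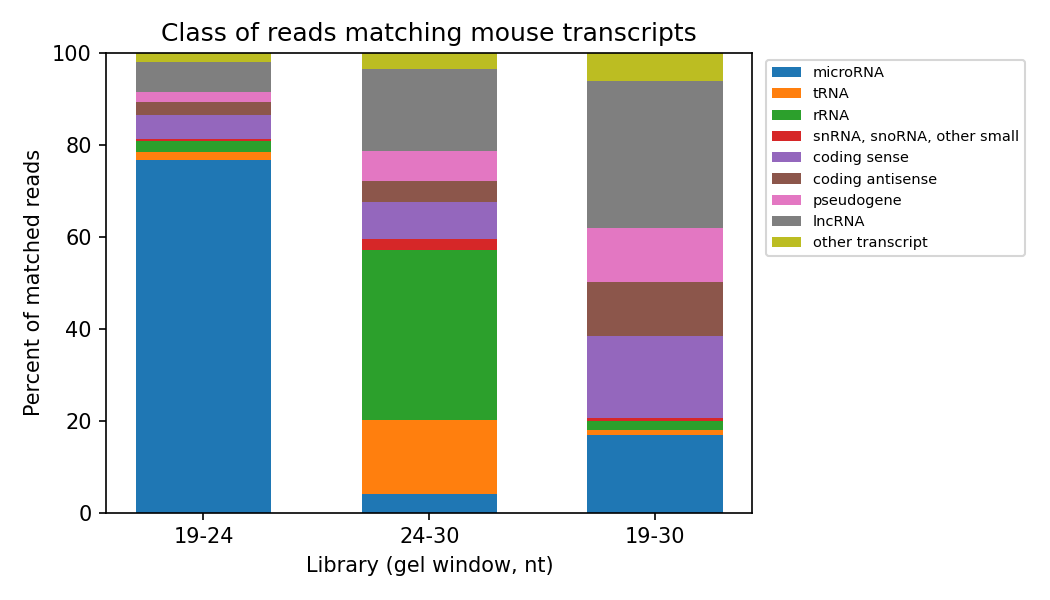
Percent of matched reads (vertical axis) by class, as stacked bars for the 3 libraries (horizontal axis). MicroRNA falls from 76.8% in the 19-24 nt library to 16.9% in the 19-30 nt and 3.96% in the 24-30 nt library.

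MicroRNAs sat in the shorter window. Over the 184 hairpins with at least 100 reads, the median ratio of the 19-24 to the 24-30 nt library was 50.9, and 10 hairpins were lower in the 19-24 nt library. Mir322 (X:53054255-53054349, GRCm38) was the most abundant, at 88747 RPM in the 19-24 nt library against 442 in the 24-30 nt library, 201-fold higher (178 to 228). Its neighbour Mir503 (X:53053984-53054054) was 57.3-fold higher (49.4 to 66.9) and Mir22 (11:75463716-75463810) 227-fold higher (193 to 269). Others among the 10 most abundant in the 19-24 nt library were Mir29a (18391 RPM), Mir21a (16755), Mir20a (16665), Mir143 (16055), Mirlet7g (15131), Mir672 (14966) and Mir130a (14630). The highest ratios were those of Mir205 (514, interval 142 to 4255), Mir98 (298, 116 to 1098), Mir547 (266, 113 to 822), Mir30b (761, 136 to 30139.5) and Mir99a (234, 166 to 340). Mir205 and Mir30b rest on 2 and 1 reads in the 24-30 nt library and were ranked with that count raised to 3, which gives 343 and 254.

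In the 24-30 nt library the most abundant hairpins were Mir541 and Mir351, both with long products. Mir541 (12:109742409-109742498) reached 6408 RPM there and 2025 in the 19-24 nt library (ratio 0.316, 0.290 to 0.344), and its 30 reads in the 19-30 nt library averaged 24.7 nt. Mir351 (X:53053255-53053353) had 6330 and 11871 RPM (ratio 1.88, 1.79 to 1.96), with 71.7% of its 46 reads in the 19-30 nt library at 24 nt or longer. Mirlet7b (2069 RPM), Gm23935, Gm24245 and Gm24270 (966 each), Mir20a (900.3), Mir30e (887), Mir672 (882) and Mir320 (627) followed in the 24-30 nt library. The lowest ratios belonged to n-TSaga9 (0.0436, 0.00775 to 0.139, on 2.67 reads in the 19-24 nt library, and 0.0491 with that count raised to 3), Gm44456 and n-TStga1 (0.0587 each, 0.0146 to 0.160), and Gm23935 and Gm24245 (0.164 each, 0.121 to 0.219). With reads sized at 19 to 24 nt alone, the ratio of Gm23935 and Gm24245 turned to 39.1 (6.45 to 1458). These are annotated as microRNA genes, and n-TSaga9 and n-TStga1 carry names of tRNA genes. Gm24270 had the same reads as Gm23935 and Gm24245. As a share of all microRNA reads the median ratio was 2.63, and Mir20a, Mir351, Mirlet7b, Mir672, Mir30e, Mir320, Mirlet7a-1 and Mirlet7a-2 were then lower in the 19-24 than in the 24-30 nt library.

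The 19-24 and the 19-30 nt library differed in which microRNAs they held, although both windows include 22 nt. In the 19-30 nt library the 10 most abundant hairpins were Mir20a (14648 RPM), Mir22 (9131), Mirlet7g (7980), Mir16-2 (7250), Mir16-1 (7217), Mirlet7i (5128), Mir294 (4666), Mirlet7a-1 and Mirlet7a-2 (4658 each) and Mir21a (4365). Mir322 had 1968 RPM there, and the 19-24 nt library was 45.1-fold higher (40.2 to 50.8). The X-linked germline cluster, a group of microRNAs found mainly in germ cells, took 3.13% of microRNA reads in the 19-30 nt library and 0.147% in the 19-24 nt library (ratio 0.0469, 0.0413 to 0.0532). All 15 of its members with at least 10 reads had the lower share in the 19-24 nt library, for example Mir741 with 89 and 194 reads and Mir470 with 24 and 103. The early embryo clusters, known from embryonic stem cells, had a ratio of 0.0496 (0.0443 to 0.0554), with 6 of 6 members lower, among them Mir294 (284 and 697 reads). Mir182, Mir183 and Mir96 together had a ratio of 0.0182 (0.0139 to 0.0234). Mir200a, Mir200b, Mir200c, Mir141 and Mir429 had 0.0922 (0.0845 to 0.101), with 3 of 5 lower. These 4 lists were also lower in the 19-24 nt library in RPM.

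The granulosa and stroma list and the blood list went the other way. The granulosa and stroma list took 9.50% of microRNA reads in the 19-24 nt library and 3.69% in the 19-30 nt library (ratio 2.57, 2.41 to 2.75), with 10 of 12 members higher in the first. Mir202 had 3658 and 14 reads, Mir503 5540 and 35, and Mir143 5161 and 127, whereas Mir21a had a slightly lower share (ratio 0.845, 0.779 to 0.918). The blood list had a ratio of 22 (13.5 to 38.6), on 16 reads in the 19-30 nt library, with 5 of 5 members higher, led by the red cell microRNA Mir451a with 3109 and 9 reads. Mir99a, Mir100 and the related Mir125 hairpins had 8.17 (6.83 to 9.85) with 6 of 6 higher, the miR-23/24/27 list 1.89 (1.75 to 2.06) with 6 of 6 higher, and the miR-15/16 list 1.52 (1.46 to 1.58) with 3 of 6 higher. Mir322 gave 28528 of the 40502 reads of the miR-15/16 list in the 19-24 nt library, and without it the ratio was 0.504 (0.483 to 0.527). Without their member with most reads, the blood list had 4.88 (2.34 to 12.2, without Mir451a), the granulosa and stroma list 6.58 (5.85 to 7.43, without Mir21a), the miR-30 list 1.07 (0.976 to 1.17, without Mir30e), the 17-92 list 0.595 (0.553 to 0.641, without Mir20a), Mir183 and Mir96 0.0345 (0.02496 to 0.0472) and the brain list 0.540 (0.395 to 0.753, without Mir138-1). Ratios below 1 that lay above 1 in RPM were those of the let-7 and miR-98 list (0.660 and 3.0), the miR-30 list (0.806 and 3.66), the 17-92 list with its paralogs (0.346 and 1.57) and the brain list (0.776 and 3.52). As a share, the liver microRNA Mir122 (2 and 4 reads, ratio 0.0512, 0.00463 to 0.357) lay on the side of the germline lists. The intervals of the brain list (0.594 to 1.03, 3 of 5 members lower) and of the muscle microRNAs (71 and 5 reads, ratio 1.45, 0.594 to 4.61) held 1. Members of a list can belong to the same cluster or carry the same counts, as Mir465c-1 and Mir465c-2 do. Random lists drew single hairpins, so the percentiles below and the counts of members do not rest on independent members. As a description of these libraries, the median of the X-linked list lay at percentile 0.01 of 10000 random lists matched on mean level, that of the early embryo list at 0.19, that of Mir182, Mir183 and Mir96 at 1.15, that of the let-7 and miR-98 list at 2.18, that of the miR-30 list at 8.65, that of the 17-92 list at 16.2, that of the miR-200 list at 17.9, that of the miR-15/16 list at 25.9, that of the brain list at 35.0, that of the miR-23/24/27 list at 73.2, that of the muscle list at 84.1, that of the granulosa and stroma list at 97.1, that of the list of Mir99a, Mir100 and Mir125 hairpins at 98.3 and that of the blood list at 99.9.

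**Figure D3:**
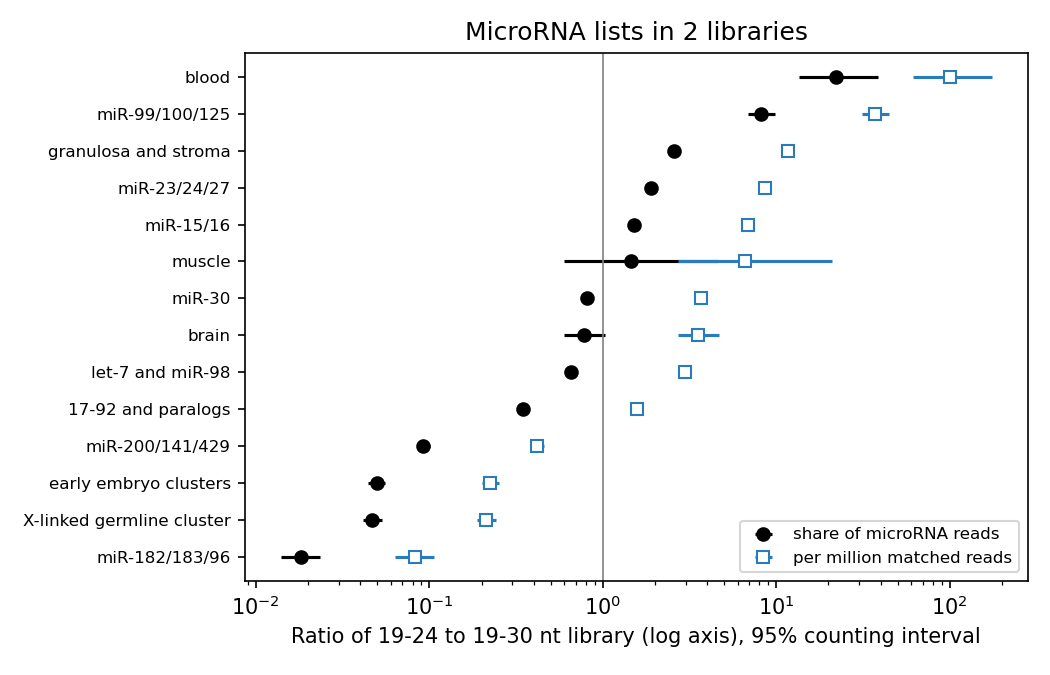
Ratio of the 19-24 to the 19-30 nt library (horizontal log axis) for each microRNA list with at least 50 reads (vertical axis), as a share of microRNA reads (filled) and in RPM (open), with 95% counting intervals. The blood list lies at 22 and the X-linked germline cluster at 0.0469 on the first scale.

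Reads antisense to coding exons address gene-derived siRNAs. They reached 143948 RPM in the 19-30 nt library (142030 to 145885), 46995 in the 19-24 nt library (46249 to 47751) and 45070 in the 24-30 nt library (44532 to 45613). Here every antisense match to a coding exon counted, also at places that took another class above. The coding antisense class alone held 11.9%, 2.71% and 4.40% of matched reads in the same order. RPM counts all matched reads, of which microRNA took 76.8% in the 19-24 nt and 16.9% in the 19-30 nt library. This scaling by itself lowers other classes in the 19-24 nt library, and a scaling without microRNA was not made. Antisense reads were 43.9% of all coding-exon reads in the 19-30 nt library (43.4 to 44.3), 39.2% in the 19-24 nt library (38.7 to 39.7) and 35.5% in the 24-30 nt library (35.2 to 35.9). This order depends on how reads with several matches are counted. With every match in full the 24-30 nt library had the highest share, and among uniquely matching reads it had by far the lowest. Counted among uniquely matching reads alone, the level was 48094, 19714 and 6204 RPM in the same order, so that the 24-30 nt library then lay well below the 19-24 nt library. Without reads that also match microRNA, tRNA, rRNA, snRNA or snoRNA genes it was 132341, 29820 and 44260 RPM, and the 19-24 nt library was then the lowest.

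Of the 8 genes whose oocyte siRNAs are known to come from pseudogenes or from paired transcripts, 6 had at least 10 weighted antisense reads, most of them 20 to 23 nt long in the 19-30 nt library. The 8 parental genes together, again per matched read including microRNA, had 5083 antisense RPM in the 19-30 nt library, 1171 in the 19-24 nt library and 9.07 in the 24-30 nt library. The 19-24 nt library was thus 129-fold (56.5 to 379) and the 19-30 nt library 560-fold (246 to 1639) above the 24-30 nt library, where these genes rest on 5.40 antisense reads. Over distinct sequences the ratios were 41.2 and 53.4, and with every match in full 38.3 and 157. Pdzd11 (X:100622883-100626568) had 228 antisense reads in the 19-30 nt library and 90 in the 19-24 nt library, all in its 5' UTR between 100626053 and 100626529. There it overlaps Kif4 (X:100625737-100727214) head to head, and Kif4, a chromosome-associated kinesin, had 134 and 56 antisense reads there, between 100626039 and 100626542. Optn (2:5020642-5064051) had 207 and 66, all in its 3' UTR between 5021012 and 5021279. Rangap1 (15:81704248-81745530), the GTPase activating protein of Ran, had 141.3 and 139.1 weighted antisense reads, nearly all in its coding sequence. Of its 719 antisense reads before weighting, 69.0% also matched the processed pseudogene Gm7162 (17:12819819-12820842) and 15.6% a microRNA hairpin. Ppp4r1 (17:65782573-65841926) had 35.5 and 19.0 antisense reads after weighting, and 90% of these reads before weighting also matched the processed pseudogene Gm15681 (8:99145386-99148089). In the 19-30 nt library 85.1% of Pdzd11, 91.8% of Optn, 97.2% of Rangap1, 88.8% of Kif4, 88.5% of Dynll1 and 77.5% of Ppp4r1 antisense reads were 20 to 23 nt long, against 83.2% of the reads assigned to the coding antisense class (82.3 to 84.1). In the 24-30 nt library Pdzd11 had 3 antisense reads, and Optn and Kif4 had 0. With that 0 raised to the floor of 3, the 19-24 nt library was 40.7-fold higher for Optn and 34.6-fold higher for Kif4. The lower limits of the counting intervals were 32.2 and 27.2. Dynll1 had 12.3 and 5.56 weighted antisense reads and Hdac1 1.14 and 0.793, and no antisense read was counted for Cdk1.

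**Figure D4:**
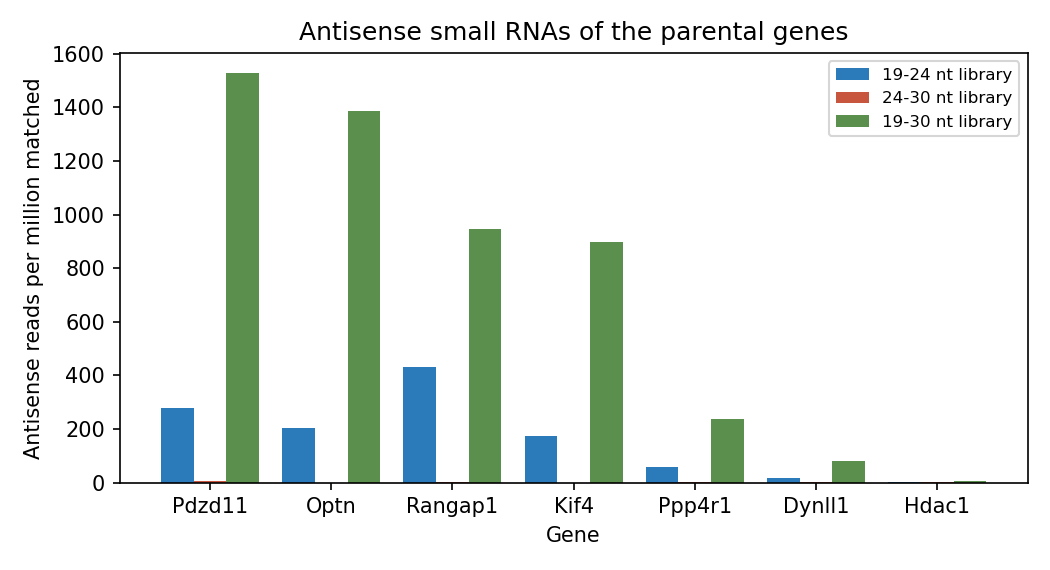
Antisense RPM (vertical axis) for 7 of the parental genes (horizontal axis) in the 3 libraries, without error bars. For 6 of these genes the 19-30 nt library is highest and the 24-30 nt library lowest, with Pdzd11 at 1526 RPM in the first, while Hdac1 lies below the level that a count of 0 allows.

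Other genes with many antisense reads fell into 3 kinds. Cd46 (3340 reads over the 3 libraries), Nlrp12 (1843) and Rtl1 (1864) had antisense reads of microRNAs: 100% of the Cd46 and Nlrp12 reads and 99.95% of the Rtl1 reads also matched a microRNA hairpin. Cwc22 (2:77881159-77946375), a splicing factor gene, had 461 and 464 antisense reads in the 19-24 and 19-30 nt library and 5 in the 24-30 nt library, between 77895869 and 77895977, and 93.5% of these reads before weighting matched a single place. C130026I21Rik, Sp140 and A530032D15Rik on chromosome 1 shared most of their reads (1014, 434 and 424 after weighting), with few in the 24-30 nt library. In the third kind, nearly all reads matched many places and the share of long reads varied. D10Wsu102e (10:83360221-83488505) led it with 9012 weighted antisense reads, 4687 of them in the 24-30 nt library and 3048 in the 19-30 nt library. Slc38a6 (2546), Gm20826 (1370), Vmn2r59 (996), Olfr784 (928), Vmn1r55 (812), Acer3 (795), Gm21244 (740), Noct (623) and Hddc3 (581) followed, whereas Asb18 (353) had 13.3 of its reads in the 24-30 nt library. Sense reads outnumbered antisense reads for D10Wsu102e (antisense share 38.2%), Noct (16.5%) and Asb18 (45.4%). For the others of this kind the antisense share ran from 80.5% (Vmn2r59) to 90.2% (Acer3). In the 19-30 nt library 44.0% of the Vmn2r59, 36.6% of the Vmn1r55 and 27.8% of the Slc38a6 antisense reads were 25 to 30 nt long, against 20.1% for Olfr784, 15.1% for D10Wsu102e, 9.95% for Acer3, 8.20% for Gm21244, 8.04% for Gm20826, 7.97% for Noct, 7.56% for Hddc3 and 2.27% for Asb18. Over the reads assigned to the coding antisense class this share was 9.10% (8.43 to 9.81).

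Reads matching the mRNAs on the fixed oocyte, ovarian cell, housekeeping and silencing lists were rare and lay mostly on the sense strand. The oocyte mRNAs, 19 of 20 found in the annotation, had 39.2, 59.2 and 31.7 weighted sense reads in the 19-24, 24-30 and 19-30 nt library, with antisense sums of 5.58, 1.30 and 6.31. The 11 granulosa and other ovarian cell mRNAs had 33.0, 93.8 and 2.01 sense reads, the inhibin genes Inhba (15, 23 and 0 reads) and Inha (7, 22 and 0 reads) being the most abundant. Housekeeping mRNAs had 39.1, 33.1 and 81.1 sense reads, led by Hsp90ab1 with 18.5, 10.7 and 51.6. The silencing machinery had 86.5, 28 and 3 sense reads, 73, 3 and 2 of them from Dgcr8. Reads that also match a microRNA hairpin were kept in these sense counts, and how many did so was not counted.

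Small RNA clusters were sought to separate siRNA-like from piRNA-like loci. Windows of 5 kb with at least 10 distinct uniquely matching sequences merged into 510 clusters, of which 258 had less than 80% of reads on 1 strand. Among the 272 clusters with at least 80% short reads, 57.0% were on both strands (51.0 to 62.7), with a median of 50% of reads starting with U. Among the 67 clusters with at least 80% long reads, 31.3% were on both strands (21.5 to 43.2), the median cluster had 93.8% of its reads on 1 strand and the median U share was 80.3%. D10Wsu102e (10:83365717-83483444) was the largest, with 4016 distinct sequences and 11626 reads, 83.5% on the plus strand (82.8 to 84.2), and it held the most short and the most long reads of any cluster. The plus strand is the sense strand of this gene. Rny3 (1643 reads) and Lars2 (2007) came next by long reads, followed by Gm17494 (3:122292965-122293039) with 579 reads and 82.2% U, Gm17821 (12:67668195-67669243) with 531 reads, all on the plus strand, and 93.2% U, Rmrp with 494, Gm48418 (12:63928156-63931750) with 418, Gm47967 (10:54212115-54216614) with 384, Noct (3:51240632-51243973) with 408 and AA474408 (7:110059763-110059869) with 346. Among the other clusters with most long reads, the U share was 89.2% in Gm48418, 73.15% in D10Wsu102e, 60.7% in Gm47967 and 54.4% in Noct. It was 30.1% in AA474408, 24.7% in Lars2, 3.29% in Rny3 and 0.202% in Rmrp. Rmrp and Rny3 encode structural RNAs. Lars2 was also among the 10 clusters with most short reads, all of its reads being on the plus strand.

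Other clusters with many short reads had a median length of 22 nt in the 19-30 nt library. The pseudogene Gm7162 (17:12818816-12820242) gave 3937 reads, 2684 of them in the 19-30 nt library, 1216 in the 19-24 nt library and 37 in the 24-30 nt library, with 93.8% on the minus strand. The cluster in Cwc22 (2:77895856-77896371) had 1724 reads split between the strands, 52.2% on the plus strand (49.8 to 54.5). Trim71 (9:114513015-114514095) was equally balanced, with 50.5% of 408 reads on the plus strand (45.7 to 55.3). Optn (2:5021009-5021305) had 60.9% of 698 reads on the minus strand and Kif4 (X:100625997-100626579) 63.1% of 515 on the plus strand. C86187 (7:46975008-46975868, 732 reads), the oocyte gene Oog4 (4:143437191-143437874, 383) and Ppp4r1 (17:65810540-65838946, 336) were almost all on 1 strand. Each of these 8 clusters had at most 37 reads in the 24-30 nt library.

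Opposite-strand reads whose 5' ends overlap by 10 nt mark piRNA-guided cleavage, and overlaps of 19 and 20 nt mark Dicer products of 21 and 22 nt. In the 24-30 nt library 162 pairs of 5' ends (138 to 189) overlapped by 10 nt, against a mean of 33.9 at the other overlaps from 1 to 24 nt, a ratio of 4.78 (z-score 10.9 as a description). Outside the D10Wsu102e cluster 75 of the 162 pairs were left, against a mean of 19.7. In the 19-30 nt library the reads of 24 nt or longer gave 9 pairs against 4.22 (ratio 2.13, z-score 2.42), the highest count being 10 pairs at 8 nt. The reads of 23 nt or longer in the 19-24 nt library, whose window ends at 24 nt, gave 30 against 29.3 (ratio 1.03, z-score 0.125). At 10 nt, the 21 and 22 nt reads of the 19-30 nt library gave 58 against 91.1 (ratio 0.637). At 19 and 20 nt, 21 and 22 nt reads averaged 113 pairs against 87.6 in the 19-30 nt library (ratio 1.29, z-score 1.57) and 40.5 against 31.2 in the 19-24 nt library (ratio 1.30, z-score 1.60). The highest count of 21 and 22 nt reads lay at 20 and at 23 nt in the 19-24 nt library (43 pairs each) and at 16 nt in the 19-30 nt library (119 pairs). Overlaps were counted as the distance between 5' ends. Values of 23 and 24 nt thus exceed the length of these reads, and they are part of the mean at the other overlaps.

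**Figure D5:**
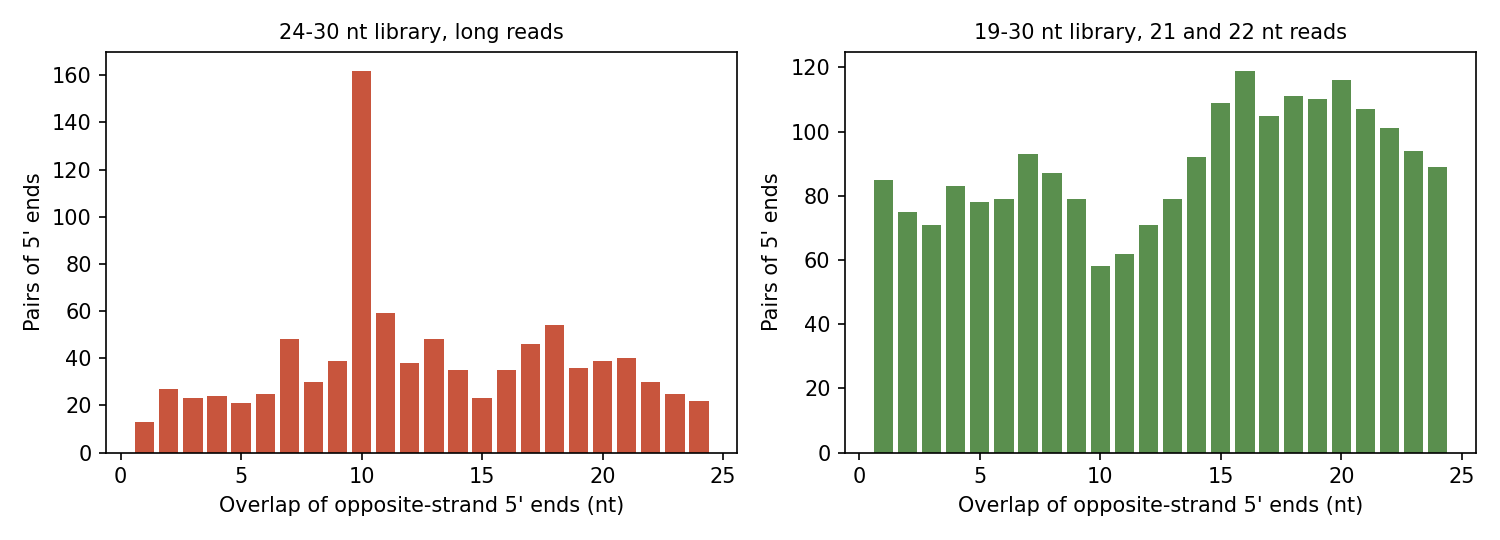
Pairs of opposite-strand 5' ends (vertical axis) by overlap in nt (horizontal axis) for long reads of the 24-30 nt library (left) and for 21 and 22 nt reads of the 19-30 nt library (right). The left plot peaks at 10 nt with 162 pairs, and the right plot has 58 pairs there.

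Sharing between libraries was counted over the first 20 nt of inserts of at least 20 nt, without size marker, bacterial and low-complexity reads. Inserts of different length with the same start count as shared, so the values do not measure the overlap of the windows. At 340021 reads per library, 62.3% of the reads of the 19-24 nt library (62.1 to 62.5) had a start also found in the 19-30 nt library, as did 52.2% of the 24-30 nt reads (52.0 to 52.4). Of the 19-30 nt reads, 55.0% were found in the 19-24 nt and 40.4% in the 24-30 nt library. Of the 19-24 and 24-30 nt libraries, whose windows meet at 24 nt, 56.0% and 59.1% of the reads were found in each other. Counting each sequence once, 13.5% of those of the 19-24 nt library were found in the 19-30 nt and 9.06% in the 24-30 nt library. Of those of the 24-30 nt library, 10.3% were found in the 19-30 nt and 10.6% in the 19-24 nt library. Across 557 coding genes, the antisense counts of the 19-24 and 19-30 nt libraries had a Pearson correlation of 0.762 on the log2 scale (Spearman 0.814), against 0.193 (0.213) for 19-24 and 24-30 nt and 0.154 (0.215) for 24-30 and 19-30 nt. Across 379 microRNA hairpins the corresponding Pearson values were 0.593 (Spearman 0.562), 0.568 (0.513) and 0.384 (0.342). These correlations are across genes, which are not independent replicates.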

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

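The test without the D10Wsu102e cluster was set before its result was seen, and the other 6 tests were chosen after the result, or values close to it, had been seen, as was the repeat without 3 oocyte genes. Reads outside the comparisons exceeded the limit that a count of 0 allows in every library. Reads with motifs taken as those of synthetic size markers numbered 21221 in the 19-24 nt, 1584 in the 24-30 nt and 48199 in the 19-30 nt library. Reads of bacterial tRNAs numbered 1940, 33810 and 22188, and in 313373 reads of the 19-30 nt library no linker was found.

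The first pattern is the 28 nt peak of the 19-30 nt library. Among reads matching mouse sequence, 28 nt was no more frequent than its neighbours (0.970 of the mean of 27 and 29 nt, 0.935 to 1.006), which argues against an oocyte RNA with a match in the transcripts searched. Within 2 mismatches over the first 20 nt, 76.5% of the 28 nt reads (76.2 to 76.8) matched the start of reads of this library counted as bacterial tRNA. Of those 22188 reads 21510 were 28 nt long, so the peak was partly compared with itself. Without mismatches these were 21510 of the 60912 reads at 28 nt. The bacterial sequences were themselves chosen after abundant unmatched reads, and many perfect matches at 28 nt, had been seen. Bacterial RNA in the library stays a candidate explanation that this comparison cannot decide, and no other biological explanation was tested.

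The second pattern is the opposite course of the germline microRNA lists and of the granulosa, stroma and blood lists in the 19-24 and 19-30 nt libraries. Among 22 nt reads alone, a length both windows hold, the X-linked germline share was still 0.0369 times that of the 19-30 nt library (0.0287 to 0.0470), which argues against the gel window. RNA of ovarian somatic cells in the 19-24 nt library stays open: granulosa and other ovarian cell mRNA reads per oocyte mRNA read were 0.843 there, 1.58 in the 24-30 nt and 0.0634 in the 19-30 nt library, 13.3 times higher in the 19-24 than in the 19-30 nt library (2.97 to 59.6), but on 2.01 granulosa reads in the latter (Inhba 15 reads against 0, Inha 7 against 0), where Nlrp5, Zar1 and Oog1 gave 25.8 of 31.7 oocyte reads, and without these 3 genes the ratio was 4.16 (0.773 to 22.4). In RPM, parental antisense reads (0.230), the X-linked cluster (0.213) and the early embryo clusters (0.225) were lower in the 19-24 nt library by similar factors. The size of these factors depends on the scaling, as microRNA took 76.8% of matched reads there and 16.9% in the 19-30 nt library. Their similarity does not, as a common scaling multiplies all of them alike. Mir182, Mir183 and Mir96 (0.0825) and the miR-200 list (0.418) had other factors. MicroRNA lists differ from each other under any scaling, so dilution by a single factor does not describe them all. The oocyte mRNAs (122 against 212 sense RPM) do not decide this. Without Nlrp5, Zar1 and Oog1 they had 23.6 reads in the 19-24 nt and 5.96 in the 19-30 nt library, which turns the direction. The X-linked share of the 24-30 nt library, of the same read length as the 19-24 nt library, was 0.00947 times that of the 19-30 nt library, but on 7 reads in a window that leaves out 22 nt, so it says nothing about the run, and run, preparation and RNA source cannot be told apart because each goes with the library.

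The third pattern is the excess of 10 nt overlaps in the 24-30 nt library. Without the D10Wsu102e cluster 75 of the 162 pairs were left, and the ratio was 3.81 (2.99 to 4.77), which argues against a single locus as the whole cause although that cluster held most of the pairs. The 21 and 22 nt reads of the 19-30 nt library had a ratio of 0.637 at 10 nt (0.484 to 0.823), which argues against matching or annotation as the cause for reads of any length. Reads of 23 nt or longer in the 19-24 nt library, with a similar number of pairs but a window that ends at 24 nt, showed no excess (ratio 1.03). What stays open is piRNA-guided cleavage, as a hypothesis found on these data, and the long reads of the 19-30 nt library gave 9 pairs at 10 nt, too few to repeat it.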

How the results depend on the processing

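First 18 nt and whole-insert matching, and first bases of matched reads outside small RNA classes, were chosen after the data were examined. No paired analysis was possible because each group holds 1 library and no test was made. Intervals are narrow at these depths, so most alternatives moved a value past its interval, and the cause was not tested unless stated. Within the stated size window, class shares were not run for the 26 nt libraries, where inserts over 22 nt have no length. Clusters were not run with 18 nt or whole-insert matching, nor overlaps with whole inserts. Sized reads of 19 to 24 nt end at 22 nt in those libraries but at 24 nt in the 19-30 nt library, which lowers their counts by construction. In the 24-30 nt library the parental genes rest on 5.40 antisense reads.

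Over distinct sequences, 34.7% of the 19-24 nt library were 18 to 22 nt, 98.1% of the 24-30 nt library 23 nt or more, and 64.4% and 21.9% of the 19-30 nt library 20 to 23 and 25 to 30 nt. Over matched reads these were 47.2%, 98.5%, 78.7% and 12.5%. The U share of distinct sequences was 41.1% (19-24), 35.8% (24-30), 51.4% and 46.2% (20 to 23 and 25 to 30 nt of 19-30), a difference of -5.16 points. Without microRNA, tRNA and rRNA it was 41.3%, 41.9%, 56.9% and 28.1% (difference -28.8). For matched reads outside small RNA classes it was 52.3%, 73.3% and, at 25 to 30 nt, 74.1%, which reversed the difference from -29.4 to 15.9 points.

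MicroRNA shares of matched reads (19-24, 24-30 and 19-30 nt library) were 84.0%, 4.86% and 34.2% with unique matches, 4.73%, 1.87% and 1.79% over distinct sequences, and 70.9%, 1.75% and 17.9% with whole inserts. With 18 nt they were 76.6% (19-24) and 16.4% (19-30). Coding antisense shares were 1.36%, 0.953% and 9.0% with unique matches, 11.9%, 8.75% and 14.5% over distinct sequences, 2.81%, 4.69% and 12.2% with 18 nt, and 3.03%, 3.95% and 11.5% with whole inserts.

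The ratio of all hairpin reads of 19-24 to 24-30 (19.4) was 76.0 with sized reads of 19 to 24 nt, 17.3 with unique matches and 40.6 with whole inserts. That of 19-24 to 19-30 (4.54) was 2.10, 2.46 and 3.97, and 4.66 with 18 nt. The median hairpin ratio (50.9) was 2.63 relative to all microRNA reads, 69.8 with sized reads and 23.6 with unique matches. Relative to all microRNA reads, the 19-24 to 24-30 ratio reversed for Mir20a (0.955), Mir351 (0.0968), Mirlet7b (0.317), Mir672 (0.876), Mir30e (0.637), Mirlet7a-1 (0.797), Mirlet7a-2 (0.854) and Mir320 (0.371), and with unique matches for Mirlet7a-1 (0.137). With sized reads it reversed for Gm23935, Gm24245 and Gm24270 (39.1 each). The 19-24 to 19-30 ratio of lists reversed relative to all microRNA reads for let-7 and miR-98 (0.660), miR-30 (0.806), 17-92 (0.346) and brain (0.776). With sized reads it reversed for miR-30 (0.396), 17-92 (0.287) and brain (0.248), and with unique matches for 17-92 (0.715) and muscle (0.677).

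Antisense RPM (19-24, 24-30 and 19-30) were 19714, 6204 and 48094 with unique matches, 630479, 1420304 and 3124627 with every match in full, 140984, 93073 and 179566 over distinct sequences, and 29820, 44260 and 132341 without structural RNA. With 18 nt they were 47981 (24-30) and 146833 (19-30), and with whole inserts 48846 (19-24) and 40159 (24-30). Antisense percentages were 28.2%, 14.7% and 37.2% with unique matches, 46.7%, 48.6% and 47.0% with every match, 30.2%, 19.0% and 38.9% over distinct sequences, and 36%, 37.5% and 42.8% without structural RNA. They were 40.04% (19-24) and 44.4% (19-30) with 18 nt and 38.6% (19-24) with whole inserts. The parental ratios to the 24-30 nt library fell to 38.3 (19-24) and 157 (19-30) with every match in full, and to 41.2 and 53.4 over distinct sequences.

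With at least 30 sequences, 137 clusters remained by construction, 74 of them on both strands, and other cluster settings kept both counts within 1.5 times. The 10 nt ratio of 24-30 was 14.0 with pairs weighted by reads and 3.25 with up to 10 matches, and that of 19-30 was 4.30 with weighted pairs. The 19 and 20 nt ratio of 19-30 was 1.49 with weighted pairs. Among sequences with at least 5 reads, 76.5% of 19-24 and 42.9% of 24-30 reads were found in 19-30, and 62.5% and 47.4% of 19-30 reads in 19-24 and 24-30. With all reads the last pair was 59.4% and 49.8%. Among the values of single hairpins, genes and lists, 224 moved, 116 stayed within their interval and 21 reversed.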

Other observations

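In the D10Wsu102e cluster, short and long reads lay mainly on the same strand, the long reads more so. On the plus strand lay 86.8% of 7711 long reads (86.0 to 87.6) and 77.0% of 3915 short reads (75.7 to 78.3). In the 170 other clusters with both sizes, 84.8% of long and 82.0% of short reads lay on the strand that led in each cluster.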
